A study of Drosophila melanogaster with 6 samples.

How the data were processed

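Germ cells were sorted from stage 16 Drosophila embryos, and 6 samples were hybridised, 3 of control PGCs and 3 of OvoA-expressing PGCs. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with a column kit including a DNase step, 10 ng was amplified with a whole transcriptome kit (Ovation PicoSL), and the product was labelled with Cy3 by a NimbleGen one-colour kit. Amplification from so little RNA can add noise, most of all for dim transcripts.

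Per the file headers, the deposited scanner files hold the spot intensity of one colour from Agilent arrays, with probe positions on dm3 (BDGP release 5). Per the submitters' processing notes they were made with Agilent Feature Extraction 10.7. Per the file headers, the processed intensity was background-subtracted, detrended within the array and replaced by a surrogate where the signal was low, with no scaling between arrays. Other columns of the same files, per the file headers, give the mean spot intensity, the median local background, and flags of 0 or 1 for spots well above background, saturated, non-uniform or outlying. The processed intensity of OvoA replicate 1 was deposited rounded to 3 significant digits, which was so for all its values and for almost none of the other arrays. The deposited value table of the series holds log2 values whose scale is not stated by the authors. Its 6 columns shared a median of 7.96 and one set of sorted values, and each ranked its spots exactly like log2 of the processed intensity of the same array (Spearman correlation 1), so it was taken as log2 of that intensity after quantile normalization, not centred by gene, with higher values for brighter spots. It was used as an alternative.

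Each array had 45019 spots, of which 43602 were not controls, with 32162 different probes. Gene names came from the accession or name in the files, matched to a table of RefSeq genes without versions: 17473 probes matched by accession, 2666 by current symbol and 919 by an older symbol, together 21058 with 1 gene name. A further 259 probes matched several genes, and these and the 10845 without a match kept the name given by the array. Control spots and spots marked non-uniform or outlying were left out, and saturated spots would have been kept. Spots of a probe were averaged. Of 32058 probes with a usable spot on every array, 30643 were kept because they were well above background on at least 3 of the 6 arrays, whichever the group. Between 92.5% and 97.5% of the spots of an array passed that background test, so it removes few dim probes, and differences at low signals are the least precise. A gene was represented by its brightest probe over all 6 arrays, and 22487 genes and transcripts were tested, 12563 with a gene name and 9924 under a clone, contig or probe name.

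Values were log2 of the processed intensity minus each array's 75th percentile. Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 with the data.table package, version 1.17.8, OvoA-expressing minus control, with no block, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. A change given as "at least N-fold" belongs to a gene that was not well above background on any array of one group. It allows for dim signals but not for the spread between arrays. The design, the members of the gene lists, the rule for named genes and all but 3 alternatives were fixed before the data were examined. The filter by median signal, the matching of list members by symbol only and the germ line lists without fs(1)K10, ovo and nanos were added as alternatives after the data were seen. The last left fs(1)K10 out of the female germline list, and ovo and nanos out of the germ plasm list. Matching by symbol or synonym only had been the first matching used, as given below. The rule named ovo, then the 12 largest rises and 12 largest falls among genes with a symbol that passed, were well above background on all 3 arrays of the brighter group and had separate groups. It added up to 3 unnamed transcripts in each direction, vas and nanos as markers of the sorted cells, and up to 4 members of each list with the lowest p.

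The 25 lists covered germ plasm and pole cell genes, the piRNA pathway, female germline and egg genes, male germline and testis genes, the JAK/STAT pathway, gonadal mesoderm, fat body, hemocytes, midgut and endoderm, muscle, neurons, glia, trichome genes, epidermis and cuticle, trachea and salivary gland, Hox and segmentation genes, Polycomb and trithorax groups, the cell cycle, cell death and p53 targets, heat shock and stress genes, antimicrobial and immune genes, cytoplasmic ribosomal proteins, oxidative phosphorylation, cell adhesion with guidance and PGC migration, and BMP, Notch, EGFR and Wnt signalling. Some genes stand in several lists, such as 15 of the adhesion list and 14 of the gonadal mesoderm list. They were tested with limma's camera (preset correlation 0.01, lists of at least 5 measured members), with an estimated correlation and with fry. Members were first matched by symbol or synonym. Matching by the array's own gene name was added after list results had been seen, which raised the number of passing lists from 9 to 10, the added one being the adhesion list (adjusted p = 0.0619 without that matching). Families of at least 10 symbols sharing a stem were tested for enrichment among the higher and lower genes by Fisher's exact test after the results were seen.

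The slide of each array, as the files give it, was treated as a batch: slide 1 held replicate 1 of both groups and slide 2 the other replicates. Whether replicate numbers pair the samples was checked from the deviations of each array from its group mean, across genes. Same-numbered arrays correlated at 0.427, 0.414 and 0.138, all over 0.1, so the numbers were taken to pair the samples. This rests on the data and not on the labels, and the arrays of each same-numbered pair also shared a slide. Alternatives were normexp background correction with an offset of 50, quantile, median and cyclic loess normalization, the value table, other background filters, every probe or the mean of the probes, slide and replicate blocks, slide 2 alone, leaving out each array, other models of the spread, other thresholds and other list tests. The fit and the list test were tested on simulated data for this comparison, with 200 of 22487 genes changed. Of 100 genes changed by 1 on the log2 scale 9 were recovered, and of 100 changed by 2 there were 93, with 4 false calls. A shifted list of 30 genes was recovered by camera, and 3 of 100 unshifted lists passed the unadjusted threshold of 0.05. Genes were simulated as independent, so this does not check the preset correlation for lists whose members move together. Estimated correlations were 0.74 for the ribosomal, 0.25 for the Hox and 0.24 for the piRNA list.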

Results

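RNA was measured in primordial germ cells (PGCs), the embryonic founders of the germ line, of Drosophila melanogaster embryos at stage 16. The cells were sorted by the green fluorescence of a Vasa reporter, which marks germ cells. There were 3 samples of PGCs expressing OvoA and 3 samples of control PGCs, each prepared from 10 ng of total RNA and hybridised to its own one-colour array. OvoA and OvoB are isoforms of the zinc finger transcription factor Ovo, and are known as a repressor and an activator of transcription. By its title, the series asked which genes are under the control of maternal OvoB in PGCs. The median processed signal ranged from 209 in control replicate 2 to 425 in OvoA replicate 1. Between 92.5% and 97.5% of the spots of an array were well above background, and 0 spots were saturated. Correlations between arrays across genes were 0.971 to 0.986 within a group and 0.954 to 0.980 between groups, and genes are not independent replicates. The number of arrays limits the precision. The labels do not say that the samples of a group were collected separately, so p-values measure the spread between these samples, which may be technical.

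The locus of the expressed isoform was examined first. The brightest ovo probe (dm3, BDGP release 5, X, 4963034 to 4963093) was 6.91-fold higher in OvoA-expressing PGCs. Its log2 signal relative to the array's 75th percentile was 4.82 ± 0.18 (SD, n = 3) in OvoA-expressing PGCs and 2.03 ± 0.10 (SD, n = 3) in control PGCs, and limma gave an adjusted p of 0.00192. The other ovo probes moved the opposite way. The probe at X, 4963614 to 4963673, fell by 3.01 on the log2 scale (SE 0.31, limma over all probes, adjusted p = 0.00566), and the probe at X, 4964679 to 4964738, fell by 2.34 (SE 0.20, adjusted p = 0.00363). Averaging the 3 ovo probes gave a log2 change of -0.85 with a limma adjusted p of 0.0895. Of the 124 called genes with more than 1 probe, 9 had probes of both signs, and ovo alone had probes called in both directions. The files do not say which exon or untranslated region a probe lies in. The germ cell marker vas, which is also the reporter's gene, had a log2 change of -0.32 (SE 0.20) that did not pass limma's test (adjusted p = 0.579). The translational repressor nanos rose by 1.15 (SE 0.19, limma adjusted p = 0.0262) at its single probe. The nanos call was lost without control replicate 2 or 3 or any 1 of the OvoA replicates, with adjusted p up to 0.134, whereas the ovo call held whichever array was left out.

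**Figure D1:**
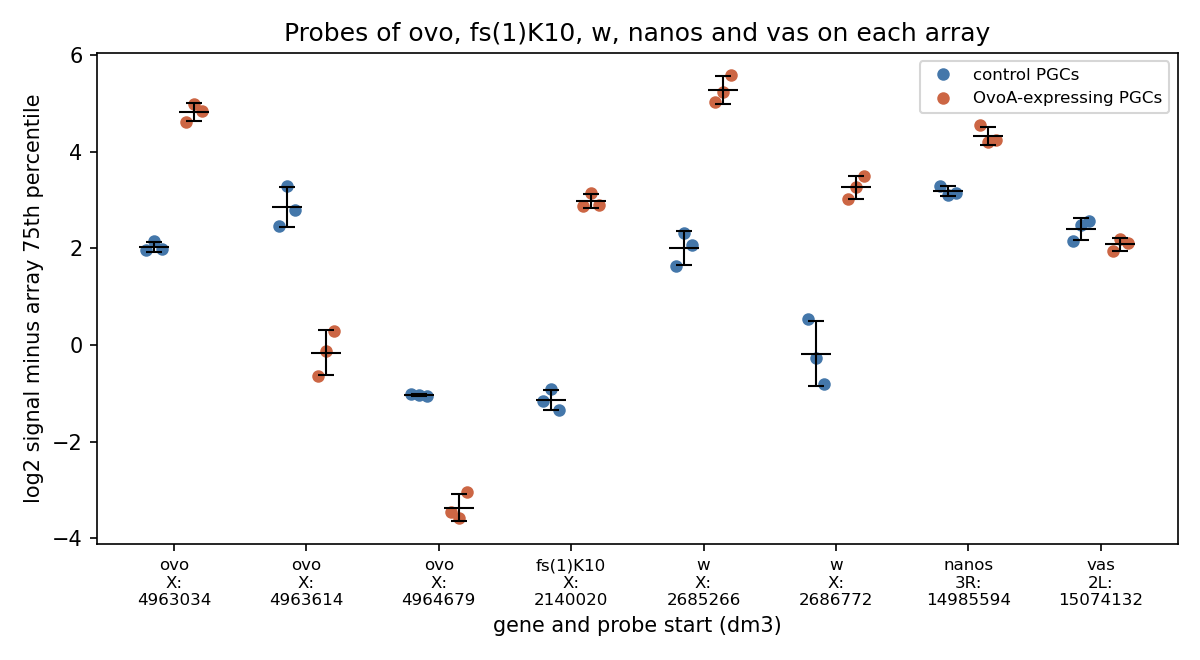
The y axis gives the log2 signal minus the array's 75th percentile, and the x axis each probe of ovo, fs(1)K10, w, nanos and vas with its dm3 chromosome and start. Points are single arrays (control PGCs in blue, OvoA-expressing PGCs in orange), and the bars give the mean and SD of 3 arrays: the first ovo probe lay higher in all 3 OvoA arrays (4.82 against 2.03), and both other ovo probes lay lower.

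Which transcripts differed between OvoA-expressing and control PGCs was then tested over 22487 genes and transcripts. In all, 260 were higher and 218 lower in OvoA-expressing PGCs (limma, Benjamini-Hochberg adjusted p under 0.05), and 249 and 208 of these changed at least 2-fold. Of the calls, 165 of the higher and 125 of the lower carried a gene name. The median log2 change was 1.52 among the higher and -1.60 among the lower. All 478 had the 3 values of one group above the 3 of the other. Passing the threshold with 3 arrays in each group nearly requires this, so it is no separate support for the calls. Groups were separate in this way for 20.1% of all tested genes, where chance gives 10%. At an unadjusted p under 0.05 there were 3151 genes, against 1124 with no effect. Of the 467 called transcripts placed on a chromosome arm, 242 had a called neighbour of the same direction within 50 kb, against at most 134 in 1000 random draws. Pairs of genes whose symbols share a family stem were not counted. The count of calls was 414 without control replicate 1, 136 without control replicate 2, 309 without control replicate 3, and 83, 162 and 175 without OvoA replicates 1, 2 and 3. With normexp background correction 232 genes passed, 41.8% of them higher against 54.4%, and the median log2 change of all genes was -0.18 against -0.05.

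Among genes with a symbol, each read at its brightest probe, the largest rise was that of fs(1)K10, which acts in the dorsoventral axis of the oocyte. Its single probe (dm3, X, 2140020 to 2140079) was 17.3-fold higher, a log2 change of 4.11 (SE 0.20, n = 3 in each group, limma adjusted p = 9.35e-04). The 38 tested genes within 50 kb of it had a median log2 change of 0.15. The white gene w, an eye pigment transporter, rose by 3.27 (SE 0.25, adjusted p = 0.00282) at one probe and by 3.45 at its second. GstD1 and GstD10, both glutathione S-transferases, rose by 3.12 (SE 0.20) and 3.50 (SE 0.43), the latter by 3.53 at its second probe. The UDP-glycosyltransferase gene Ugt302C1 rose by 3.76 (SE 0.25). Another, Ugt35E2, was not well above background on any control array and was at least 7.67-fold higher. Such a bound sets the brighter group's mean against a mean of, per array, the higher of the dim probe's own signal and the lowest signal well above background. It leaves out the spread between arrays and the choice of background correction, so the change can be smaller. Members of either family are alike in sequence, so a probe can also read a paralog. The mitochondrial import gene Tim17a1 rose by 4.0 (SE 0.36), and by 2.79 at its second probe. Its brighter probe and those of GstD10, GstD9 and GstD1 lie between 8189510 and 8193611 on dm3 3R. The Golgi kinase fj rose by 3.61 (SE 0.51), and by 3.15 at its second probe, and fng, a glycosyltransferase that modifies Notch, by 2.81 (SE 0.39), with 1 of 3 control arrays well above background. The basement membrane protein nidogen, Ndg, rose by 3.22 (SE 0.26), and D2hgdh, a dehydrogenase of D-2-hydroxyglutarate, by 3.05 (SE 0.25). PPYR1 was not well above background on any control array and was at least 4.13-fold higher. The 3 largest rises without a gene name were TC242579 with 3.56, beside the Ugt302C1 probe on 3R, and TC225442 with 3.46 and A_09_P195625 with 3.42, which lie side by side on 2L. With normexp the calls of Ugt35E2 (0.17), D2hgdh (1.22), fng (0.47), TC242579 (1.71) and TC225442 (1.30) were lost, and PPYR1 changed sign (-0.11). Tim17a1 (2.21), Ugt302C1 (2.21) and fj (1.83) kept their calls with normexp at changes more than 1.5 times smaller. Leaving out 1 array ended the calls of fj (control replicate 2 or any OvoA replicate, adjusted p up to 0.0833), PPYR1 (the same 4 arrays, up to 0.0947), GstD10 (any OvoA replicate, up to 0.0585), fng (OvoA replicate 1 or 2, up to 0.0764) and Ugt35E2 (OvoA replicate 1, 0.0694).

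By measured signal at each gene's brightest probe, the largest fall of a gene with a symbol was that of fs(1)M3, a protein of the vitelline membrane of the egg. Its probe (dm3, X, 5852293 to 5852352) was not well above background on any OvoA array, and its signal was at least 11.3-fold higher in control PGCs (limma adjusted p = 0.00129, n = 3 in each group). The odorant receptor gene Or98a was also not well above background on any OvoA array and was at least 6.68-fold higher in control PGCs (adjusted p = 0.00565). How its fall and that of fs(1)M3 rank is therefore uncertain. BigH1, the linker histone of early embryos and germ cells, fell by 2.71 (SE 0.22). The phenylalanine hydroxylase gene Hn fell by 2.79 (SE 0.24), glutamine synthetase Gs1 fell by 2.49 (SE 0.27) and cystathionine beta-synthase Cbs fell by 2.45 (SE 0.22). The 2 other Hn probes stood at -1.74 and -1.59, and the last did not pass (limma over all probes, adjusted p = 0.0624). The glutathione S-transferase GstE1 fell by 2.64 (SE 0.29), while its second probe, at -0.82, did not pass. The gene olf413 fell by 2.56 (SE 0.27) at its brighter probe, and its other probe stood at 0.26. The transporter gene rumpel fell by 3.00 (SE 0.57) and superdeath fell by 2.71 (SE 0.24). The probes of mmm and t-Grip84, which fell by 2.59 (SE 0.34) and 2.56 (SE 0.41), lie between 7580226 and 7581909 on dm3 3L on opposite strands. The second mmm probe stood at -1.34, and the second t-Grip84 probe, at -2.59, did not pass (limma over all probes, adjusted p = 0.0706). Whether the labelled product kept its strand is not given in the sources used here, so overlapping and antisense transcripts could not be told apart. By measured signal, the largest falls without a symbol were A_09_P194145, at least 8.40-fold higher in control PGCs, NP1340850, which fell by 3.90, and CG12426, at least 12.9-fold higher in control PGCs. The probes of NP1340850, Or98a and CG12426 lie between 23604061 and 23697354 on dm3 3R, so these falls come from one stretch of the chromosome. With normexp the calls of fs(1)M3 (-1.25), Or98a (-1.0), mmm (-1.45), t-Grip84 (-1.44), A_09_P194145 (-1.23) and CG12426 (-1.45) were lost. Leaving out any 1 array ended the call of rumpel (adjusted p up to 0.157), leaving out OvoA replicate 1 or 2 those of mmm (up to 0.0720) and CG12426 (up to 0.0577), and leaving out either of these or control replicate 2 those of NP1340850 (up to 0.0948) and of t-Grip84 (up to 0.0921), which was also lost without OvoA replicate 3.

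**Figure D2:**
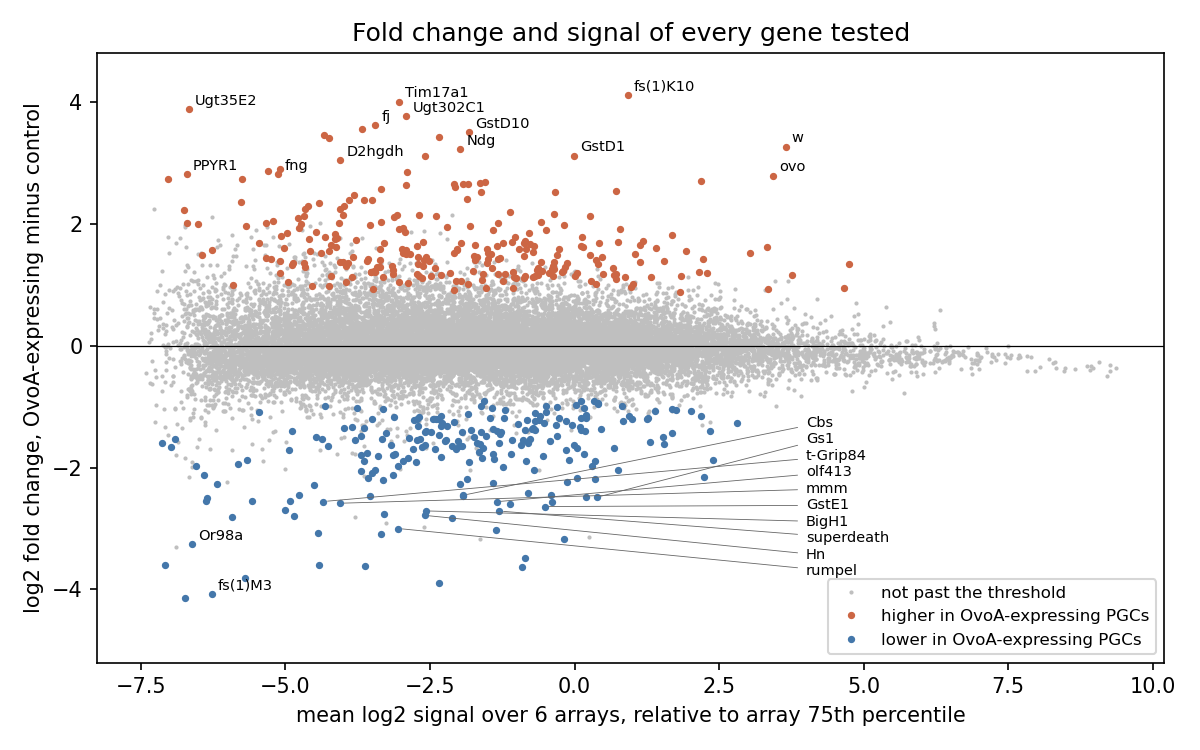
The y axis gives the log2 fold change (OvoA-expressing minus control PGCs) of each of the 22487 genes and transcripts, and the x axis its mean log2 signal over the 6 arrays, relative to each array's 75th percentile. Orange points are the 260 higher and blue points the 218 lower transcripts, grey points did not pass, and the genes with the largest changes, such as fs(1)K10 at 4.11, are named, with measured values also for genes such as fs(1)M3 that were not well above background in one group and have only a bound there.

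Of 25 gene lists fixed before the data were examined, 10 shifted against all other genes (limma camera with a preset correlation of 0.01, Benjamini-Hochberg over the lists), 6 upwards and 4 downwards. The adhesion list passed only once members were also matched by the array's own gene name. That matching was added after list results had been seen. With an estimated correlation 0 of the 25 passed after adjustment, with a lowest adjusted p of 0.355, and 2 had an unadjusted p under 0.05. By limma's fry, which asks whether a list's own genes move one way and does not compare them with other genes, 2 lists passed (the stress and the female germline lists), and 20 passed its test for change in either direction. The shifts given below are means of log2 changes over a list's measured members.

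Of the 5 lists of germ line and cell cycle genes, 3 fell. Among 37 genes of the piRNA pathway, which silences transposons in the germ line, 5 fell and 0 rose over all genes tested, and 11 fell and 1 rose adjusted over the list alone. The list mean was -0.39 (camera adjusted p = 9.87e-06, and adjusted p = 0.463 with an estimated correlation). The members that fell were squ (-1.61), tej (-1.20), aub (-1.19), Boot (-1.19) and, named after its values were seen, qin (-1.07). Of the 36 female germline and egg genes, 4 fell and 1 rose, and 6 fell and 3 rose adjusted over the list alone. Their mean was -0.27 (camera adjusted p = 0.00600, and adjusted p = 0.355 with an estimated correlation). Those that fell were fs(1)M3 (at least 11.3-fold higher in control PGCs), the yolk protein receptor gene yl (-2.0), the maternal cell cycle regulator gnu (-1.63) and the RNA-binding protein gene orb (-0.99), while fs(1)K10 rose by 4.11. Of 41 cell cycle genes 3 fell, namely gnu, Cdk4 (-1.33) and RnrS (-1.20), and 9 fell adjusted over the list alone. The mean was -0.35 (camera adjusted p = 9.87e-06, and adjusted p = 0.463 with an estimated correlation). Among 26 germ plasm and pole cell genes, ovo at its brightest probe and nanos rose and orb fell, while the 2 other ovo probes fell, so that the direction of ovo depends on the probe. In this list 4 rose and 4 fell adjusted over the list alone, and the list did not pass (camera adjusted p = 0.247). It passed as lower with every probe tested (shift against all genes -0.23, camera adjusted p = 0.00217), with the mean of a gene's probes (-0.22, adjusted p = 0.00321) and, an alternative chosen after the data were seen, without ovo and nanos (-0.20, adjusted p = 0.0139), against a shift of -0.03 with both. Of 34 male germline and testis genes, nht (-1.42) fell, 2 rose and 3 fell adjusted over the list alone, and the list did not pass either (adjusted p = 0.247), but did as lower with normexp (shift -0.17, camera adjusted p = 0.0388). Without control replicate 3 the shift against all genes went from -0.38 to -0.23 for the piRNA pathway, from -0.34 to -0.21 for the cell cycle and from -0.26 to -0.16 for the female germline list, which no longer passed (adjusted p = 0.162). With normexp these 3 shifts were -0.22, -0.17 and -0.10, and the calls of aub (-1.10) and orb (-0.91) were lost along with that of fs(1)M3. Of the genes called here, fs(1)K10, fs(1)M3 and ovo kept their calls whichever array was left out. Apart from qin, for which this was not run, the others lost theirs in at least 3 of the 6 leave-outs, with a highest adjusted p of 0.169 (aub without control replicate 2). With the replicate number as a block, aub (0.0513) and orb (0.0513) did not pass.

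All 86 cytoplasmic ribosomal protein genes had a negative log2 change, and none of them passed the test, over all genes or adjusted over the list alone. Their mean was -0.25 (camera adjusted p = 5.14e-06, and adjusted p = 0.763 with an estimated correlation). The 245 other genes as bright as they were had a median of -0.16, and 81.6% of these were negative. The shift against all genes, -0.23, was -0.05 with normexp (camera adjusted p = 0.0527), -0.10 with quantile normalization or the value table and -0.11 with loess. It was -0.15 without control replicate 3, -0.13 without OvoA replicate 2 and -0.38 without OvoA replicate 3. The 31 genes of oxidative phosphorylation had a mean of -0.09 and did not pass (adjusted p = 0.372), and 0 members changed by either adjustment.

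Of 6 lists of stress, signalling and patterning genes, 4 rose. Of 28 heat shock and stress genes, 4 rose and 0 fell, and 7 rose adjusted over the list alone. The mean was 0.48 (camera adjusted p = 5.14e-06, and adjusted p = 0.355 with an estimated correlation). The 4 were GstD1 (3.12), the translation inhibitor Thor (1.63), GstD2 (1.56) and CG4456 (1.30), listed under the older name Hsp67Bb. Of the 4, 2 are thus glutathione S-transferases, and CG4456 alone was listed under a heat shock name. Of 16 measured genes whose symbols share the stem Hsp, 0 were called in either direction, and their median log2 change was 0.12. Of 35 genes of BMP, Notch, EGFR and Wnt signalling, aop (1.22) and E(spl)m7-HLH (1.20) rose, and 7 rose adjusted over the list alone. The mean was 0.21 (camera adjusted p = 0.00858, and adjusted p = 0.355 with an estimated correlation). Of 26 genes of cell adhesion, guidance and PGC migration, the laminin gene LanA (1.68), the integrin gene scb (1.52) and nanos rose, and 7 rose adjusted over the list alone. The mean was 0.25 (camera adjusted p = 0.0234, and adjusted p = 0.355 with an estimated correlation). Of 34 Hox and segmentation genes, Abd-B (1.85), abd-A (1.52) and Kr (1.15) rose, and 4 rose adjusted over the list alone. The mean was 0.22 (camera adjusted p = 0.0434, and adjusted p = 0.763 with an estimated correlation). The second abd-A probe rose by 4.44. Of 25 genes of cell death and p53 targets, rpr (2.12), Xrp1 (1.69) and Buffy (1.15) rose, 5 rose and 1 fell adjusted over the list alone, and the list did not pass (adjusted p = 0.437), but did as higher with normexp (shift 0.24, camera adjusted p = 0.0388). Of 20 JAK/STAT genes, the feedback inhibitor Socs36E rose by 2.61 (SE 0.25, limma adjusted p = 0.00506), 1 rose and 2 fell adjusted over the list alone, and the list did not pass (adjusted p = 0.428). With the replicate number as a block, the adhesion list (adjusted p = 0.0588), the Hox list (0.0927) and the gene Kr (0.0601) did not pass, and with the slide as a block the Hox list did not (0.0653). The adhesion list was also lost without control replicate 1 (0.0595) or 2 (0.0862) or OvoA replicate 1 (0.0564) or 3 (0.0509), and the Hox list without control replicate 2 (0.0862) or 3 (0.308) or OvoA replicate 1 (0.153) or 3 (0.0509). With normexp the shift of the Hox list against all genes went from 0.24 to 0.06 (adjusted p = 0.683), and the calls of GstD2 (0.25), E(spl)m7-HLH (1.09), scb (1.06), abd-A (1.12), Kr (0.21), rpr (1.31) and Buffy (0.63) were lost. Of the genes called here GstD1 and Socs36E kept their calls whichever array was left out, and the rest lost theirs in at least 3 of the 6 leave-outs, with adjusted p up to 0.196 (Buffy without control replicate 2).

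Mean changes of the lists of other cell types ran from 0.37 in glia to -0.10 in the midgut. Of 19 glial genes, Mdr65 (1.76) and Gli (1.13) rose, 3 rose adjusted over the list alone, and the mean was 0.37 (camera adjusted p = 0.00103, and adjusted p = 0.355 with an estimated correlation). The glial genes Eaat1 (-0.11), wrapper (-0.26) and repo (-0.28) did not pass. Of 29 hemocyte genes, LanA rose and 2 rose adjusted over the list alone. The hemocyte mean was 0.19 with a median of -0.01 (camera adjusted p = 0.0377, and adjusted p = 0.463 with an estimated correlation). The other 7 lists of cell types did not pass. Among 28 genes of the gonadal mesoderm, Abd-B and abd-A rose, 4 rose and 1 fell adjusted over the list alone, and the mean was 0.08 with a median of -0.01 (adjusted p = 0.541). Of 29 neuronal genes Fas2 fell by 1.87 (SE 0.19), 3 rose and 1 fell adjusted over the list alone, and the list's adjusted p was 0.293. In the midgut (29 genes, adjusted p = 0.493), epidermis (54 genes, adjusted p = 0.613) and muscle (33 genes, adjusted p = 0.976) lists, yip7 (-1.40), kkv (-1.82) and mspo (-1.71) fell, and 1 gene fell adjusted over each list alone. The muscle list had a mean of -0.02 and a median of 0.01, with camera's direction upwards. In the trachea and salivary gland list (23 genes, adjusted p = 0.636, mean 0.06, median -0.03) and the fat body list (24 genes, adjusted p = 0.963), 0 genes changed by either adjustment. With normexp the midgut (shift against all genes -0.20, camera adjusted p = 0.0391) and epidermis (-0.18, adjusted p = 0.0313) lists passed as lower. With every probe tested the gonadal mesoderm (0.37, camera adjusted p = 0.00166) and muscle (0.23, adjusted p = 0.0136) lists passed as higher, as did the gonadal mesoderm list among genes above the median signal (0.33, adjusted p = 0.0192). With the replicate number as a block, the hemocyte list (adjusted p = 0.0588), Gli (0.0581) and mspo (0.0558) did not pass, and the hemocyte list was lost without control replicate 2 (0.107) or 3 (0.108) or OvoA replicate 3 (0.117). With normexp the shift of the glial list against all genes went from 0.38 to 0.24, and the calls of Gli (0.43), Mdr65 (0.20), abd-A (1.12), yip7 (-0.88) and mspo (-0.97) were lost. Fas2 and kkv kept their calls whichever array was left out, while the other genes called here lost theirs in at least 3 leave-outs, with adjusted p up to 0.169 (Gli without control replicate 2).

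Of the remaining lists, the 29 antimicrobial and immune genes included PGRP-SD, which fell by 2.05, and the antifungal peptide gene Drs, which rose by 0.92. In this list 2 rose and 2 fell adjusted over the list alone, and it did not pass (camera adjusted p = 0.728). Of 31 Polycomb and trithorax genes, Su(z)2 rose by 1.64, as it did adjusted over the list alone. That list had a mean of 0.02 and a median of -0.12 (adjusted p = 0.963). Of 19 trichome genes 0 changed by either adjustment, and the list did not pass (adjusted p = 0.963). With the replicate number as a block PGRP-SD (adjusted p = 0.0553) and Drs (0.0691) did not pass, and with the slide as a block Drs (0.0526) did not. With normexp the calls of PGRP-SD (-1.35) and Drs (0.60) were lost. The call of Drs was lost whichever array was left out (up to 0.206), that of PGRP-SD in 5 of the 6 leave-outs (up to 0.158) and that of Su(z)2 without control replicate 2 or OvoA replicate 1 or 2 (up to 0.0675).

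**Figure D3:**
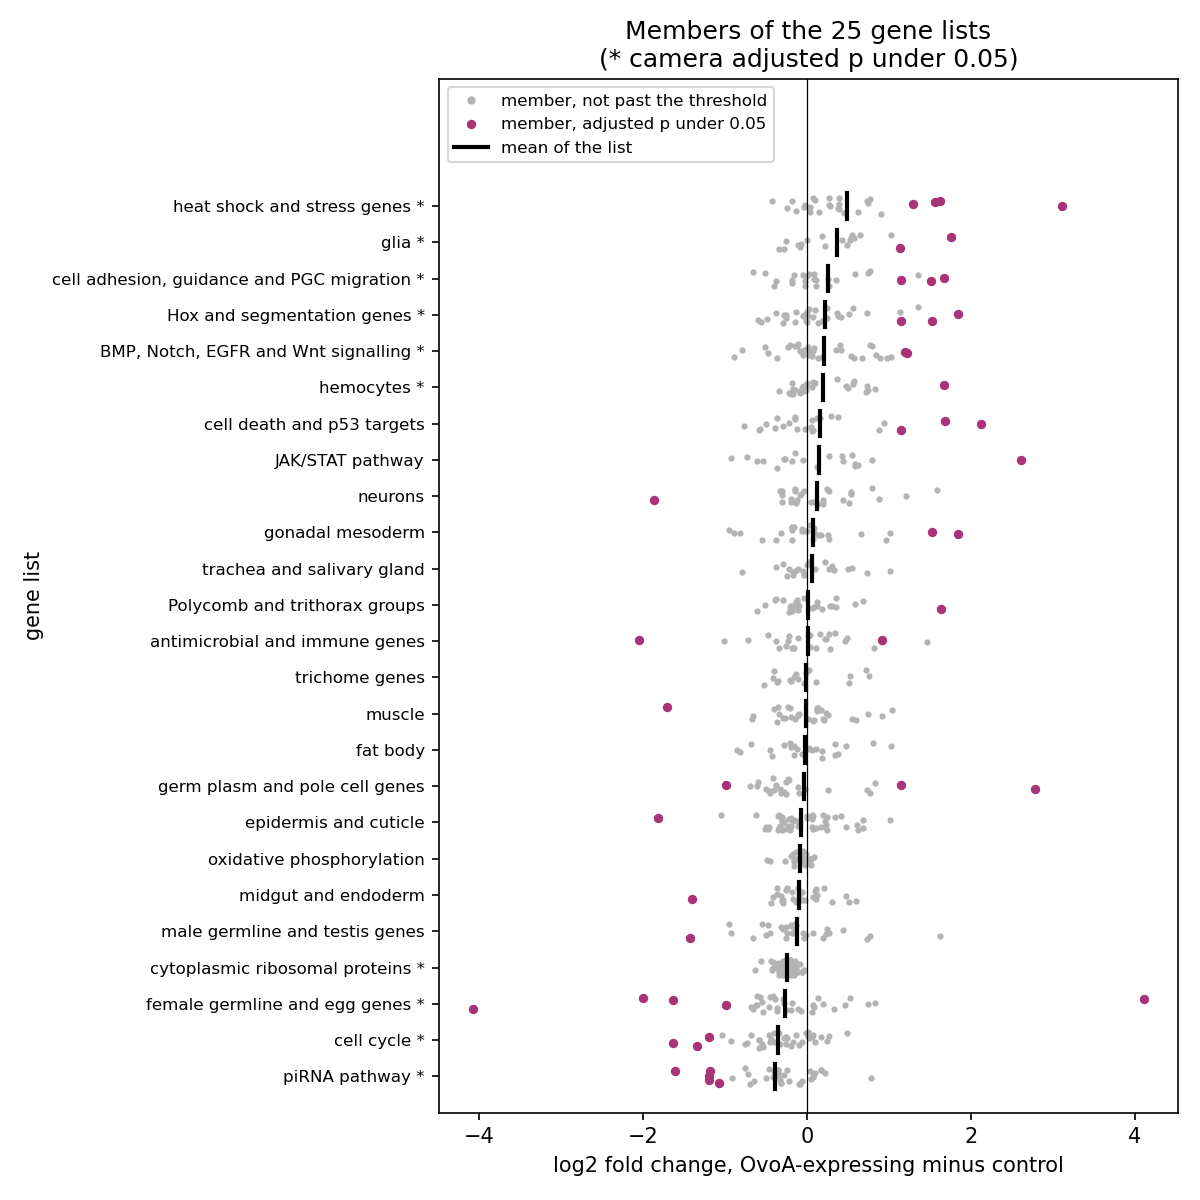
Each row is 1 of the 25 gene lists and the x axis gives the log2 fold change (OvoA-expressing minus control PGCs) of each measured member. Points are genes (purple where the adjusted p was under 0.05), the black mark is the mean of the list, and an asterisk marks the 10 lists that passed camera with the preset correlation: means ran from -0.39 in the piRNA pathway to 0.48 in the stress genes.

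The arrays lay on 2 slides, slide 1 with replicate 1 of both groups and slide 2 with replicates 2 and 3 of both. With the slide as a block 568 genes passed limma's test, and 149 did within slide 2, while slide 1 held 1 array of each group and allowed no test. The brightest ovo probe rose by 2.67 within slide 1 and by 2.85 within slide 2. Shifts against all genes of the 10 lists that passed with the preset correlation, of which 0 passed with an estimated correlation (lowest adjusted p = 0.355), had the same sign within both slides. Within slide 1 and slide 2 these were -0.16 and -0.27 for the ribosomal proteins, -0.13 and -0.50 for the piRNA pathway, -0.08 and -0.47 for the cell cycle, and -0.12 and -0.33 for the female germline genes. They were 0.56 and 0.47 for the stress genes, 0.22 and 0.46 for glia, 0.19 and 0.24 for BMP, Notch, EGFR and Wnt signalling, 0.35 and 0.22 for adhesion, 0.09 and 0.27 for hemocytes, and 0.17 and 0.27 for the Hox genes. Within slide 2 alone the adhesion list did not pass camera (adjusted p = 0.0884), and the oxidative phosphorylation list did, as lower (adjusted p = 0.0306). Among lists that did not pass, shifts differed in sign between the slides for oxidative phosphorylation (0.18 and -0.20), the germ plasm genes (0.17 and -0.13) and the Polycomb and trithorax genes (0.23 and -0.07), among others.

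X-linked and autosomal genes were compared because the sex makeup of the sorted cells was not given. The median log2 change was -0.04 over 3694 X-linked and -0.04 over 17410 autosomal genes, a difference of 0.00347 (two-sided exact permutation test over the 10 splits of the arrays, p = 0.8, smallest possible p 0.1). The sign of the difference turned without control replicate 1 (-0.0147) or 3 (-0.000763) or OvoA replicate 2 (-0.0150) or 3 (-0.00385).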

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

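The filter by median signal and the germ line lists without fs(1)K10, ovo and nanos were chosen after seeing the data. Matching of list members by symbol or synonym only was the first matching used. It became an alternative when matching by the array's own gene name, which the 10 passing lists rest on, was added after list results were seen. The other alternatives were fixed before. The count of 478 changed genes was 232 with normexp, 149 within slide 2 and 83 to 414 with 1 array left out (fewer arrays), and 841 with trend and robust estimation, 2436 with array weights, 865 at an adjusted p under 0.1 and 897 at an unadjusted p under 0.05 with at least 2-fold change. It lay between 397 and 637 under the other alternatives run, and the cause of the differences was not tested. Normexp kept 230 of the 478 calls. With the replicate number as a block, 487 genes passed, 392 of them shared with the 478. Among the 10 passing lists and the 64 called genes it was run for, which leave out qin and those given under other observations alone, the paired fit ended the calls of the adhesion, hemocyte and Hox lists and of aub, Gli, Kr, orb, PGRP-SD, Drs and mspo, and no others. The 10 passing lists became 0 with an estimated correlation, 2 with fry's directional test, 20 with its test for either direction, 7 with the replicate block, 7 to 10 with 1 array left out, 9 with matching by symbol only, 12 with normexp, 13 with every probe tested, 11 with the mean of a gene's probes and 11 without fs(1)K10, ovo and nanos in the germ line lists. The list gained in the last 2 of these was that of germ plasm genes, as lower, which was also gained with every probe tested along with the gonadal mesoderm and muscle lists. When nanos was left out of the germ plasm list it stayed in the adhesion list, which was not tested without it. With normexp the male germline, midgut and epidermis lists were gained as lower and the cell death list as higher. The Hox list also did not pass with normexp (adjusted p = 0.683), quantile (0.0637) or loess (0.0504) normalization, the value table (0.0625), no filter (0.0502) or the strictest filter (0.0724), nor the hemocyte list with quantile (0.0637), loess (0.0563) or the value table (0.0625). Among genes above the median signal the female germline (0.239), adhesion (0.0601) and Hox (0.0855) lists did not pass. No passing list changed direction in any alternative. The rise of the brightest ovo probe was 2.70 to 2.88 with 1 array left out and passed under every alternative run for it but the mean of the 3 probes, which joins probes of opposite sign (-0.85). The X to autosome difference ran from -0.0150 to 0.0318 with 1 array left out (-0.0147, -0.000763, -0.0150 and -0.00385 where it turned). With normexp the signs of PPYR1 (-0.11), Mst87F (-0.36), Gad1 (-0.032), kni (-0.29), Gasp (-0.061) and Osi7 (-0.065) turned. Of these PPYR1 had passed, and 26 of 64 called genes were lost. The normexp offset of 50 exceeds the median processed signal of negative controls (1.45 to 2.52), so by construction it shrinks changes of dim genes. The 75th percentile of the processed intensity was 1670 and 1104 in OvoA replicates 1 and 2, and 846 in OvoA replicate 3. In controls it was 787 to 974. Normexp starts instead from the mean spot intensity and the local background, whose percentiles were not examined. If those percentiles rank the arrays alike, a fixed offset would place dim genes lower, relative to them, in OvoA replicates 1 and 2. How much of the normexp differences this accounts for was not tested. Of the 31 genes and transcripts other than ovo that were named for size or as markers and had passed, 14 kept their call under all alternatives run for them. Signals near background limit the dimmest genes most: 6 called genes were not well above background on any control array and 8 on any OvoA array.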

Other observations

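Glutathione S-transferases, enzymes that conjugate glutathione to reactive compounds, rose as a family beyond the genes already named. Of 35 measured members 10 rose and GstE1 alone fell, against 122 higher genes among 7366 with a symbol (one-sided Fisher's exact test over 57 families in both directions, chosen after the results were seen, adjusted p = 1.58e-08). The 10 were GstD1, GstD2, GstD3, GstD6, GstD9, GstD10, GstE5, GstE6, GstE7 and GstE14. Among these GstE6 rose by 2.64 (SE 0.20), GstE5 by 2.17 (SE 0.25), GstE7 by 1.93 (SE 0.18) and GstD9 by 1.90 (SE 0.22) by limma. Other members of the same clusters, such as GstD8 (-0.01) and GstE2 (-0.32), did not pass. All 10 kept positive changes with normexp, but 6 passed and the smallest of the 10 changes was 0.03, against 1.39, while 9 or all 10 passed under each of the 4 other scalings. Since neighbours in a cluster are alike in sequence, the members are not independent. Among 30 UDP-glycosyltransferases 4 rose and the family did not pass (adjusted p = 0.0802).

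Calls on the X chromosome were more often falls than calls on the autosomes. Of the X-linked calls 67 were lower and 34 higher (66.3% lower), against 146 lower and 220 higher on the autosomes (39.9% lower), a comparison chosen after the counts were seen (Fisher's exact test, p = 2.98e-06, odds ratio 2.96). The share was higher on the X in all 5 scaling and background alternatives, at 82.0% against 52.0% with normexp and 60.3% against 38.7% with the value table. Called neighbours are not independent, so this p is too small, and the medians of all X-linked and autosomal genes differed by 0.00347. No explanation was tested.

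In the patterns weighed next, the tests of slide, of the ovo probes, of the share of germ cells and of glia were chosen only after the result was seen. The first pattern is the set of 478 changed genes. The 10 splits of the arrays are too few for a share under 0.05; the real split gave 478 genes and the highest of the other 9 gave 0, as did the 3 others that part every numbered pair. A difference between slides is argued against, since each slide held as many arrays of one group as of the other, and 149 genes passed within slide 2 alone, a count already known when this test and its bound of 5% of 478 were set in place of a fit with the slide as a block, which 568 genes passed but which cannot decide in so balanced a layout. Strain variants in chromosome segments that differ between the crosses may account for a part, because 242 of 467 placed calls had a called neighbour of the same direction within 50 kb against at most 134 in 1000 random draws of as many genes (permutation p = 0.000999, the smallest these draws can give), and 76 of 289 did among gene names alone, against at most 70. These counts leave out pairs of genes whose symbols share a family stem, in the data and in the draws. Unnamed features of one transcript and neighbours under common control would also raise these counts, and the effect of OvoA itself, which the design names, stays open and untested.

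The second pattern is that the brightest ovo probe, fs(1)K10, w and nanos rose while 2 other ovo probes fell. A shared rise of the whole segment around fs(1)K10 is argued against. Its 38 tested neighbours within 50 kb had a median log2 change of 0.15. A median cannot speak to a variant that changes only some genes of the segment. Among the neighbours 1 passed, SmydA-8 at 2.24, so fs(1)K10 has a called neighbour of the same direction. The gene w had only 5 tested neighbours, with a median of -0.79 and a highest change of 0.28, so less can be said of its segment. Over both genes the 43 neighbours had a median of 0.11. Neighbours cannot speak to a variant confined to either gene itself. A hypothesis is that the transgene carries sequences of these genes: germ line expression vectors often hold an fs(1)K10 3' end and a white marker, and germ line drivers hold nanos sequences, but the labels name neither vector nor driver. On this reading the rising ovo probe may read a transgene that lacks the part under the other probes, of which the less lowered stood at -2.34; since the idea came from the same probes it cannot be told apart from other changes at the locus. The falls of the 2 other probes would then be of ovo transcripts that hold the part under them, unless a sequence variant under both lowered their signal, and neither was tested.

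The third pattern is the shift of gene lists, with the piRNA, female germline and cell cycle lists lower and the stress and glial lists higher at the preset correlation, while 0 of 25 lists passed with an estimated correlation (lowest adjusted p = 0.355). Whether a lower share of germ cells, with more of every other cell type, lay behind this could not be decided. The means of the 9 other cell type lists ran from 0.37 in glia to -0.10 in the midgut (permutation test of their range, 100000 draws, p = 0.0235). That test deals genes as independent, though estimated correlations were 0.24 in the midgut and 0.32 in the epidermis list, so its p is too small. Muscle (-0.02, SE 0.09), fat body (-0.02, SE 0.09) and epidermis (-0.08, SE 0.06) were not above 0. Shifts against all genes of muscle and epidermis were -0.16 and -0.20 within slide 1, but 0.07 and 0.005 within slide 2. With every probe tested the muscle (0.23) and gonadal mesoderm (0.37) lists passed as higher. Unequal amounts of other cell types would also give unlike lists. Glial cells passing the sort for the Vasa reporter may explain Gli and Mdr65, but these 2 calls were lost with normexp (0.43 and 0.20), 7 of the 19 glial genes had a change that plus 1 SE lay under 0.5 times that of Gli less 1 SE, among them repo (-0.28) and Eaat1 (-0.11), which did not rise, and the brightest glial genes Nrx-IV (0.54) and loco (0.53) did not pass. That is too mixed to decide, 3 of the 19 also stand in other lists, and how many of them germ cells also express was not examined. A direct or indirect effect of OvoA on these genes stays open and untested.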
